A study of Mus musculus with 6 samples.

How the data were processed

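Total RNA from 6 samples of mouse enterospheres, 3 kept with T3 and 3 without, was measured on Affymetrix Mouse Gene arrays, 1 array per sample. The labels write the T3 dose with the unit nm, which was read here as nM. Groups and replicate numbers were taken from the sample labels, and each sample pooled cells from 3 newborn mice. The labels do not say whether arrays of the same number in both groups came from one preparation, and of the 3 samples of a group they say only that each used 3 mice. T3 was added to a part of the dishes per the labels' protocols, so a shared preparation is possible, and p-values measure the spread between these samples.

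The authors deposited log2 expression values per probe set, 35556 in all, with RMA and Partek version 6.5 as the tools in the submitters' processing notes. RMA as usually run corrects background, normalizes arrays by quantiles and summarises the probes of a probe set. Their settings, the probe set level and the genome build are not given in the sources used here, so no coordinates are printed. Quantile normalization aligns the distributions of the arrays, which removes any change common to most genes, and array background compresses differences of dim genes, so that a fold change here is a fold of normalized signal and tends to understate the change of a dim gene. The values carry no detection calls, so it is not known which probe sets were above background.

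Probe sets were named through the array's platform annotation. It gave 1 gene symbol to 21789 probe sets, several to 1621, and did not list 12146. For 21698 of the 21789 the gene identifier was in a current gene table and for 91 it was not; no symbol was newer there. Probe sets with several names or none entered no gene-level test. A gene with more than 1 probe set (999 genes) was represented by the one with the highest mean over the 6 arrays, which left 19938 genes. Listed genes without a probe set of their own single name were not analysed here. Genes of families with similar sequence, such as the guanylate-binding proteins, can share probe signal, which was not examined further.

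Each gene was tested for T3 minus control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend, robust fitting or a filter on dim genes), two-sided, with Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05, and every adjusted p of a single gene in the text comes from limma. Errors given as SE are those of the limma log2 change, and errors given as SD are over the 3 arrays of a group. For 25 gene lists, the shift against all other genes was tested with camera at a preset correlation of 0.01, adjusted over the lists, for lists with at least 5 measured genes. Beside it stand the counts of called members over all genes and adjusted over the list alone, camera with a correlation estimated from the arrays, and fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes. Some genes stand on several lists, such as Thrb, Edn3, Kcna1 and Kcnj10. The comparison, the lists, the rule for named genes and the alternative settings other than those named as added were fixed before the data were examined.

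By that rule the text names, of the called genes with non-overlapping groups, the 10 with the largest log2 change in each direction, always Klf9, Hr, Dio3, Thra and Thrb, and of each list up to 4 genes of smallest unadjusted p. Genes outside it that the text names were chosen after their values were seen: Kcnj10, Cacna1g, Insm1, Dcx, Tubb3, Elavl4 and Uchl1, Gfra3, Gfra2 and Igf1 among neurotrophic genes, Sostdc1, Myh11, P4ha2, Pdgfrb, Col6a1, and the genes of the additional observations that are on no fixed list. So were Dio1, Ucp1, Thrsp, Fasn and Me1, given as examples of dim or bright genes, and Kit, Etv1, Hcn4 and Thbs4.

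The procedure was tested on simulated data with the 19938 genes, 3 arrays against 3 and 200 changed genes in each of 20 runs. It recovered 54.5% of changes of 0.5 on the log2 scale, 91.2% of changes of 1 and 98.7% of changes of 1.5, with the right sign in 100% of those called, and 4.18% of the calls were false. With no change put in, the mean number of genes and of lists called was 0. The simulated genes were drawn independently of each other, so the 0 for lists does not cover lists whose genes move together. In the real data the estimated correlation within a list reached 0.448, for G2/M and mitosis genes.

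No pair of arrays was a duplicate: the SD of the difference between 2 arrays of a group over all genes was 0.137 to 0.243, against 0.223 to 0.267 between groups, and at most 21 genes had identical values. Alternatives tried were the replicate number as a block, a renewed quantile normalization, centring on the median or the 75th percentile, leaving out the dimmest 25% or 50% of genes, the mean of a gene's probe sets, each probe set on its own, limma with trend and robust fitting, array quality weights, adjusted p under 0.10, unadjusted p under 0.05 with at least 1.5-fold change, and leaving out each array in turn. Covariates for the sex mix of the pools and a test of all probe sets together were added after seeing the data.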

Results

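Gene expression was measured in enterospheres, free-floating clusters of neural progenitor cells grown from the muscle layer of the gut of newborn C57BL/6 mice. The spheres had been moved from growth medium to differentiation medium before the hormone was added. Group T3 held 3 samples kept for 1 day with triiodothyronine (T3) at 100 nM (as the unit, written nm in the labels, was read here), the form of thyroid hormone that binds its nuclear receptors, and the control group held 3 samples kept without it. Each sample came from 3 mice and was hybridised to 1 whole-transcript mouse expression array. The array medians lay between 6.09 and 6.15 on the log2 scale. The number of arrays, 3 per group, limits the precision of the values. The design compares T3 with no T3 and so asks which genes respond to the hormone in whole spheres kept in differentiation medium. Besides neural genes the spheres carried signal of fibroblast and mesenchyme genes. The mean control log2 value was 9.94 for that list, 9.76 for enteric neural progenitor markers and 8.79 for neuron markers. A change can therefore not be placed in a particular cell type.

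T3 changed the level of 618 of the 19938 genes tested, 3.10%, and more of them rose than fell. With an adjusted p under 0.05, 454 genes were higher and 164 were lower in the T3 samples. Most changes were moderate: 57 of the higher and 11 of the lower genes differed by at least 2-fold, and the median log2 change was 0.56 among the genes that rose and -0.53 among those that fell. The groups of 3 values did not overlap for any of the 618 genes. Over all genes, the groups did not overlap for 3881, or 19.5%, against 10% by chance for 3 against 3. An unadjusted p under 0.05 was reached by 2737 genes where 996.9 would be reached by chance. The first principal component held 41.3% of the variance and separated the T3 arrays, at -16.0 to -11.1, from the control arrays, at 10.4 to 14.6. The second, with 24.3%, separated control replicate 2, at -17.6, from control replicate 3, at 16.2. As their groups did not overlap, all 618 genes had to keep their direction when any 1 array was left out. This is therefore no check of the calls. Of the 618 genes, 173 passed the test in each of those 6 fits. The number called was 395 without T3 replicate 1, 262 without T3 replicate 2, 256 without T3 replicate 3, 191 without control replicate 1, 640 without control replicate 2 and 405 without control replicate 3. Of the calls, 73.5% were higher, against 81.5% after centring each array on its median and 67.6% after centring on its 75th percentile.

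**Figure D1:**
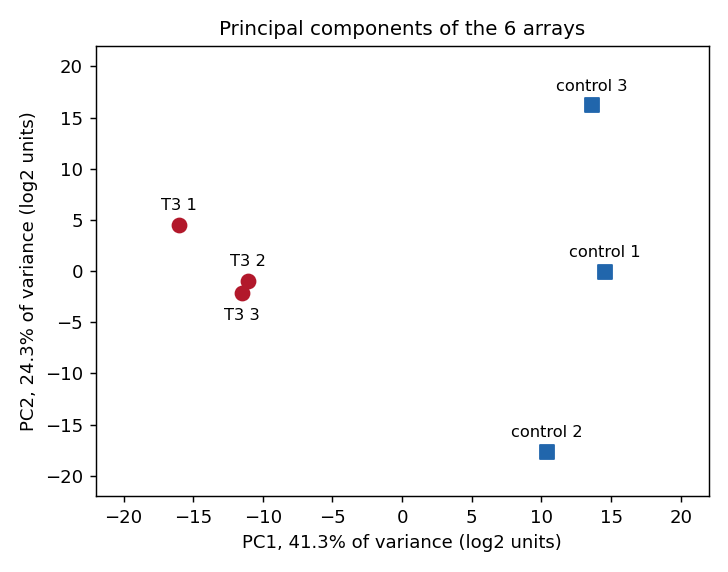
First and second principal components of the 6 arrays over all genes tested, in log2 units, with T3 arrays as circles and control arrays as squares. All 3 T3 arrays lie below 0 on the first component and all 3 control arrays above it, while control replicates 2 and 3 lie farthest apart on the second.

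The largest rise in signal was that of Cdh12, a cadherin of the neuronal cell surface (probe set 10423258), with a log2 value of 4.51 ± 0.11 (SD, n = 3) in controls and a log2 change of 2.49 ± 0.09 (SE) with T3, a 5.63-fold difference in signal. Its control value lay near the 25th percentile of the arrays (4.47 to 4.53) and is not known to be above background, so this fold and its rank are those of the signal and can understate the change. Kcna1, a voltage-gated potassium channel (probe set 10548047), rose 3.87-fold, and Hr, a corepressor of nuclear receptors (probe set 10416302), rose 3.78-fold. They were followed by the synaptotagmin gene Syt12 with a log2 change of 1.89, the transcription factor Klf9 with 1.86, the orphan receptor gene Gpr50 with 1.85, the guanylate-binding protein gene Gbp3 with 1.82, Cacng5, which encodes an auxiliary subunit of glutamate receptors, with 1.80, the pancreatic polypeptide receptor gene Npy4r with 1.73 and Edn3, a ligand of the endothelin B receptor, with 1.69. The standard errors of these 10 changes lay between 0.07 for Kcna1 and Hr and 0.18 for Gpr50. Adjusted p (limma) ran from 1.28e-05 for Cdh12, Kcna1 and Hr to 0.00182 for Gpr50, and all 10 passed the test without any 1 array.

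Among the genes that fell, Ccn2, a secreted matricellular protein (probe set 10362201), went from 10.58 ± 0.08 (SD, n = 3) to 8.86 ± 0.13 (SD, n = 3), a fall of 3.30-fold with adjusted p = 9.01e-05 (limma). Its family member Ccn1 had a log2 change of -1.04 ± 0.09 (SE). Sox11, a transcription factor of immature neurons (probe set 10399725), changed by -1.21 ± 0.07 (SE) with adjusted p = 0.000176. The other large falls were those of Apela, a peptide ligand of the apelin receptor, at -1.80, the carboxypeptidase-like gene Cpxm2 at -1.43, the myelin gene Opalin at -1.31, the homeobox gene Alx4 at -1.25, the proteoglycan gene Kera at -1.13, the cadherin gene Cdh13 at -1.12 and the predicted gene Gm10825 at -1.02. The calls of Apela, Opalin and Gm10825 depended on single arrays. The call of Apela was lost without T3 replicate 2, control replicate 1 or control replicate 3 (adjusted p up to 0.0723), that of Opalin without T3 replicate 2 or any control array (up to 0.148), and that of Gm10825 without T3 replicate 3 or control replicate 1 (up to 0.0702).

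**Figure D2:**
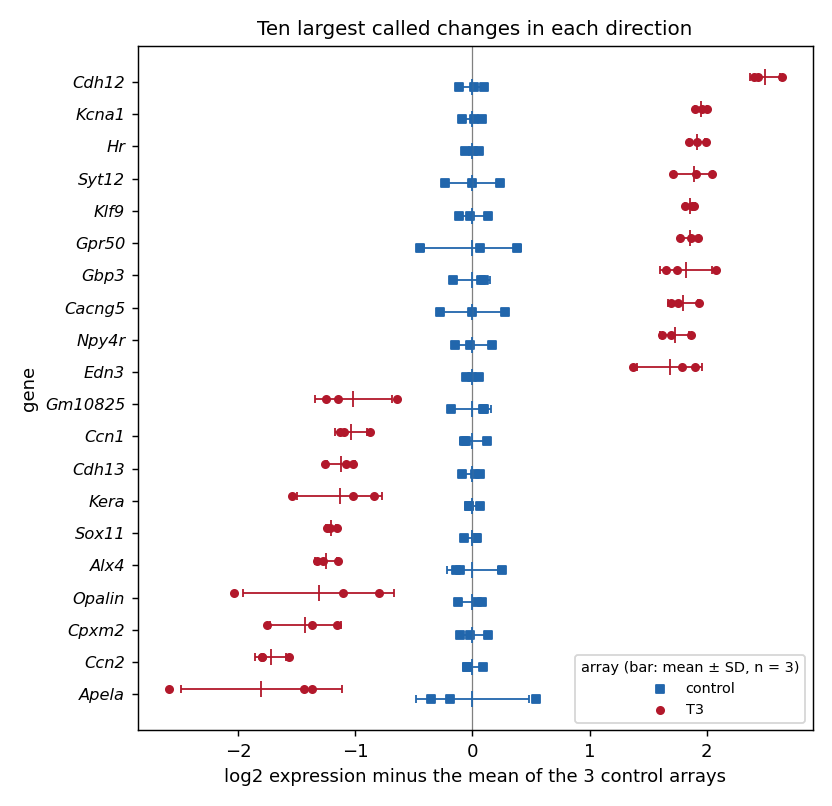
Log2 expression on each array minus the mean of the control arrays (horizontal axis, log2 units) for the 10 largest called changes in each direction; points are arrays, ticks are group means and bars are SD with n = 3. The T3 and control values of each gene do not overlap, and the T3 values of Apela and Opalin are the most scattered.

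Known thyroid hormone-responsive genes were shifted upwards as a group. Of 35 measured genes on this list, 11 rose, 1 fell and 23 did not pass over all genes; adjusted over the list alone, 13 rose and 1 fell. Hr and Klf9 led with log2 changes of 1.92 ± 0.07 (SE) and 1.86 ± 0.08 (SE), followed by Gbp3, by Thrb, the thyroid hormone receptor beta gene, at 1.30 ± 0.08 (SE), by the clock output gene Dbp at 0.98 and by Ppargc1a, a coactivator of mitochondrial genes, at 0.93. The gene that fell was Kcnj10, a potassium channel of glia, at -0.49. The call of Kcnj10 was lost without any array except control replicate 2 (adjusted p up to 0.153). The median of the list was 0.10 and its mean 0.34. Against all other genes the list was shifted upwards by camera (adjusted p = 1.44e-05), and adjusted p = 0.263 with an estimated correlation.

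Genes of thyroid hormone receptors, coregulators, transporters and deiodinases included 1 receptor gene that rose. Thrb rose 2.46-fold from a log2 value of 4.95 ± 0.10 (SD, n = 3), whereas Thra, at 11.59 ± 0.01 (SD, n = 3) in controls, had a log2 change of -0.09 ± 0.06 (SE) and adjusted p = 0.652 (limma); the difference between their changes was not tested. Crym, which encodes a cytosolic T3-binding protein, was lower at -0.68 ± 0.12 (SE), a call lost without T3 replicate 3, control replicate 1 or control replicate 3 (adjusted p up to 0.0740). Dio3, the deiodinase that inactivates thyroid hormone, had a log2 change of 0.54 ± 0.15 (SE) and did not pass (adjusted p = 0.120), nor did Rxrg at 0.50 (adjusted p = 0.0614). Of 18 measured genes, 1 rose, 1 fell and 16 did not pass; adjusted over the list alone, 3 rose and 1 fell. The list as a whole was not shifted (camera, adjusted p = 0.781).

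Neuron markers were shifted upwards as a group. Of 40 measured genes, 9 rose, 2 fell and 29 did not pass; adjusted over the list alone, 18 rose and 3 fell. Prph, an intermediate filament of peripheral neurons, rose 1.92-fold with a log2 change of 0.94 ± 0.10 (SE). The peptide gene Cartpt rose by 0.77 ± 0.12 (SE), Dbh, which makes noradrenaline, by 0.91 ± 0.14 (SE), and Chga, of secretory granules, by 0.51 ± 0.08 (SE). The 2 that fell were genes of immature neurons, Insm1 at -0.37 ± 0.07 (SE) and Dcx at -0.36 ± 0.07 (SE). The general neuronal genes Tubb3, Elavl4 and Uchl1, chosen after their values were seen, had log2 changes of 0.03, 0.02 and -0.02 with adjusted p of at least 0.952, and the sign of such small changes turned with the scaling or the arrays used. Prph passed without any 1 array. The calls of Cartpt (without T3 replicate 3 or control replicate 1), Dbh (without T3 replicate 2 or 3) and Chga (without T3 replicate 1, T3 replicate 3 or control replicate 1) were lost with adjusted p of up to 0.0692, that of Insm1 without any array but control replicate 2 (up to 0.0982) and that of Dcx without any 1 array (up to 0.177). The list median was 0.23 and the shift passed by camera (adjusted p = 1.52e-05), with adjusted p = 0.350 with an estimated correlation.

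Genes of ion channels and transporters of excitable cells were also shifted upwards as a group. Of 27 measured genes, 8 rose, 2 fell and 17 did not pass; adjusted over the list alone, 10 rose and 3 fell. Besides Kcna1, the potassium channel gene Kcnj8 rose 2.06-fold, the sodium channel gene Scn3a rose 1.66-fold and Hcn2, a hyperpolarisation-activated channel, rose 1.59-fold, and these 4 passed without any 1 array. The 2 genes that fell were Kcnj10 at -0.49 and the calcium channel gene Cacna1g at -0.60 ± 0.12 (SE). Cacna1g lost its call without any 1 array (adjusted p up to 0.102) and Kcnj10 without any except control replicate 2 (up to 0.153). The median was 0.21 (camera, adjusted p = 1.52e-05, and adjusted p = 0.216 with an estimated correlation).

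Enteric neural progenitor markers did not shift as a list. Edn3 rose 3.22-fold and Phox2a, a transcription factor of autonomic neurons, rose by 0.58 ± 0.08 (SE), while the other 18 of 20 measured genes did not pass; adjusted over the list alone, 3 rose and 2 fell. Sox8 had a log2 change of -0.41 (adjusted p = 0.0562) and Ret one of 0.26 (adjusted p = 0.139). The call of Phox2a was lost without control replicate 1 (adjusted p = 0.0527). The median was -0.0071, the mean was 0.08 and camera gave a downward direction that did not pass (adjusted p = 0.869), so the signs differed.

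Enteric glia and Schwann cell markers moved both ways, with 5 of 23 measured genes higher, 1 lower and 17 not passing; adjusted over the list alone, 5 rose and 2 fell. Kcna1 and Lgi4, a secreted protein of myelinating glia with a log2 change of 0.60 ± 0.07 (SE), passed without any 1 array. Gfra3 at 0.59, Gpr37l1 at 0.42 and Sostdc1 at 0.39 were also higher and Kcnj10 was lower at -0.49. Those 4 calls were lost in at least 3 of the 6 fits without 1 array, all 4 both without T3 replicate 3 and without control replicate 1 (adjusted p up to 0.182 over the 6 fits). The list was not shifted (median 0.01; camera, adjusted p = 0.535). Markers of interstitial cells of Cajal, the pacemaker cells of the gut, were shifted upwards. Of 8 measured genes, Prkcq at 0.73 ± 0.09 (SE) and Ano1, a chloride channel, at 0.43 ± 0.08 (SE) were called. The other 6 did not pass: Gja1 and Cacna1h at 0.24 and 0.21, Kit, Etv1 and Hcn4 at 0.08, 0.07 and 0.02, and Thbs4 at -0.17. The counts adjusted over the list alone were again 2 and 0. This shift (median 0.14; camera, adjusted p = 0.0111) had adjusted p = 0.469 with an estimated correlation, and it was lost without T3 replicate 2 (adjusted p = 0.0625) or control replicate 3 (adjusted p = 0.0936). Ano1 lost its call without any array except control replicate 2 (adjusted p up to 0.145).

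Markers of the other cell types that gut muscle can hold gave mixed values and no shift. Of 17 smooth muscle genes, Tagln at -0.72 ± 0.09 (SE) and Acta2 at -0.38 ± 0.08 (SE) were lower, Myl9 at 0.50, Myocd at 0.54 and Myh11 at 0.60 were higher and 12 did not pass (median 0.26; camera, adjusted p = 0.280); adjusted over the list alone, 8 rose and 3 fell. Of these 5, Tagln alone passed without any 1 array, while Acta2 and Myh11 passed in none of the 6 such fits, Myl9 only without control replicate 3, and Myocd only without T3 replicate 3 or control replicate 3 (adjusted p up to 0.165). Of 19 fibroblast and mesenchyme genes, Thy1, a surface protein also found on neurons, rose 2.36-fold, Sfrp1 rose by 0.45 and Twist1 was lower at -0.49, with 16 not passing (median -0.04; camera, adjusted p = 0.418); adjusted over the list alone, 3 rose and 4 fell. Sfrp1 lost its call without T3 replicate 3 or control replicate 1 (adjusted p up to 0.0842) and Twist1 without any array except control replicate 1 (up to 0.117). Of 15 endothelial genes, Egfl7 fell by 0.70 and Kdr by 0.41 on the log2 scale, Plvap rose by 0.42 and 12 did not pass (median 0.09; camera, adjusted p = 0.781); the counts adjusted over the list alone were the same. Kdr was lost without T3 replicate 2, T3 replicate 3 or control replicate 1 (adjusted p up to 0.0776) and Plvap without any T3 array or control replicate 1 (up to 0.114).

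No marker of macrophages and leukocytes (19 genes), epithelium (15 genes) or mesothelium (9 genes) passed the limma test, over all genes or adjusted over the list alone, and the 3 lists were not shifted (camera, adjusted p = 0.560, 0.781 and 0.869). At an unadjusted p under 0.05 the lists held 2, 1 and 2 genes. Their mean control log2 values were low, at 5.14, 5.14 and 5.43, below the median of every array. Whether these genes were above background is not known. The lack of calls therefore does not show that such cells were present and unchanged. The macrophage gene of smallest p was Coro1a, with a log2 change of 0.31 and adjusted p = 0.0699.

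Genes of mitosis were shifted upwards together by small amounts, with none passing singly. Of 31 measured genes of G2/M and mitosis, 28 had a log2 change above 0, with a median of 0.23 (camera, adjusted p = 8.71e-07, and adjusted p = 0.433 with an estimated correlation). The largest of the 4 with the smallest p were Nusap1 at 0.47 ± 0.13 (SE, adjusted p = 0.109) and Anln at 0.35 ± 0.09 (SE, adjusted p = 0.0729), followed by Top2a at 0.34 and Aurka at 0.26; the limma count was 0 over all genes and adjusted over the list alone, while 16 genes, all higher, had an unadjusted p under 0.05. None of 33 G1/S and DNA replication genes (median 0.03; camera, adjusted p = 0.280) and none of 18 cell cycle inhibitors and antiproliferative genes (median -0.07; camera, adjusted p = 0.175) passed either way, with 4 and 2 genes at an unadjusted p under 0.05.

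Genes of the Notch pathway and neurogenic transcription factors were shifted downwards. Hey1, a Notch effector, fell by 0.39, Notch2 by 0.36 and the proneural factor Neurod4 by 0.71 on the log2 scale, Id2 rose by 0.44, and 20 of 24 measured genes did not pass; adjusted over the list alone, 3 rose and 7 fell. The shift (median -0.06; camera, adjusted p = 0.0438) had adjusted p = 0.433 with an estimated correlation. It was lost without T3 replicate 1, T3 replicate 2, control replicate 2 or control replicate 3 (adjusted p from 0.0515 to 0.0993), without the dimmest 25% or 50% of genes (0.0564 and 0.0790) and with array quality weights (0.211). Each of the 4 single calls was lost without any 1 of the T3 arrays and without control replicate 1 (adjusted p up to 0.202).

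Neurotrophic ligands and receptors moved both ways. Edn3 rose as above, Ntrk2, a neurotrophin receptor, rose by 0.53 ± 0.08 (SE), and Egfr and Met, receptors of epidermal and hepatocyte growth factor, fell by 0.64 and 0.76 on the log2 scale. Igf1 at 0.68, Gfra3 at 0.59 and Gfra2 at 0.39 were the other genes that rose. Of 34 measured genes, 5 rose, 2 fell and 27 did not pass (median 0.0045; camera, adjusted p = 0.468); adjusted over the list alone, 8 rose and 4 fell. Edn3 and Egfr passed without any 1 array, whereas Ntrk2, Met, Igf1, Gfra3 and Gfra2 each lost their call without T3 replicate 3 and without control replicate 1 (adjusted p up to 0.144 over the 6 fits).

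The lists of glycolysis and hypoxia genes and of oxidative phosphorylation genes were shifted upwards by camera, with few members called. Of 28 measured genes of glycolysis and hypoxia, 5 rose and none fell, with Pfkfb3, a regulator of glycolysis, at 0.77 ± 0.12 (SE), the peptide gene Adm at 0.51, the oxygen sensor gene Egln3 at 0.48, Higd1a at 0.53 and P4ha2 at 0.45; adjusted over the list alone, 7 rose. The median was 0.11 (camera, adjusted p = 0.000804, and adjusted p = 0.263 with an estimated correlation), and the shift was lost without the dimmest 50% of genes (adjusted p = 0.0737). These 5 single calls were each lost without T3 replicate 3 and without control replicate 1 (adjusted p up to 0.170 over the 6 fits). Of 36 measured genes of oxidative phosphorylation and mitochondria, 32 had a change above 0, and Ppargc1a at 0.93 ± 0.11 (SE) and Idh3a at 0.33 ± 0.07 (SE) were called, as they were adjusted over the list alone (median 0.10; camera, adjusted p = 0.000285, and adjusted p = 0.525 with an estimated correlation). Idh3a lost its call without any 1 array (adjusted p up to 0.139). Of 28 genes of cholesterol and fatty acid synthesis, Insig1 alone was called, at -0.43, also adjusted over the list alone and lost without any 1 array (adjusted p up to 0.158), and the list was not shifted (camera, adjusted p = 0.535).

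Interferon response genes were shifted upwards, with 16 of 17 measured genes above 0. Oasl2 rose by 0.66 ± 0.09 (SE) and Ifit3 by 0.85 ± 0.13 (SE), 15 did not pass, and adjusted over the list alone 4 rose (median 0.19; camera, adjusted p = 4.61e-05, and adjusted p = 0.216 with an estimated correlation). Oasl2 was lost without control replicate 1 (adjusted p = 0.0520) and Ifit3 without T3 replicate 2 or control replicate 1 (up to 0.0588).

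Of 29 extracellular matrix proteases, inhibitors and glycoproteins, Mmp9, a gelatinase, rose 1.82-fold, and Plau, Mmp14 and Adamts1 fell by 0.56, 0.41 and 0.40 on the log2 scale; adjusted over the list alone, 2 rose and 6 fell. The list was not shifted (camera, adjusted p = 0.0630). Plau lost its call without T3 replicate 2 or 3, Mmp14 without any array except control replicate 2, and Adamts1 without any 1 array (adjusted p up to 0.141). Of 17 clock genes, Dbp rose 1.97-fold and Nfil3, a repressor at the same promoter element, was lower at -0.59, which was lost without T3 replicate 2, control replicate 1 or control replicate 3 (adjusted p up to 0.129); the counts adjusted over the list alone were the same (camera, adjusted p = 0.781). Of 27 immediate early and stress genes, Egr2 alone was called, at -0.64 ± 0.10 (SE), also adjusted over the list alone and lost without control replicate 1 (adjusted p = 0.0567), and the list was not shifted (camera, adjusted p = 0.0630).

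In all, 9 of the 25 lists passed camera with a preset correlation between genes of 0.01, and none passed with the correlation estimated from these 6 arrays. By fry, which asks only whether a list's genes moved on balance one way, 8 lists passed, among them the hormone-responsive, neuron, ion channel, interferon and glycolysis lists. The lists of interstitial cell, mitosis, Notch and oxidative phosphorylation genes did not pass fry (adjusted p = 0.0699, 0.116, 0.116 and 0.116). Glia and neurotrophic genes upwards and matrix genes downwards passed fry but not camera (adjusted p = 0.0142, 0.0467 and 0.0467). Centring each array anew moves every log2 change by 0.03 or -0.02, so the sign of list medians this close to 0 is not settled.

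**Figure D3:**
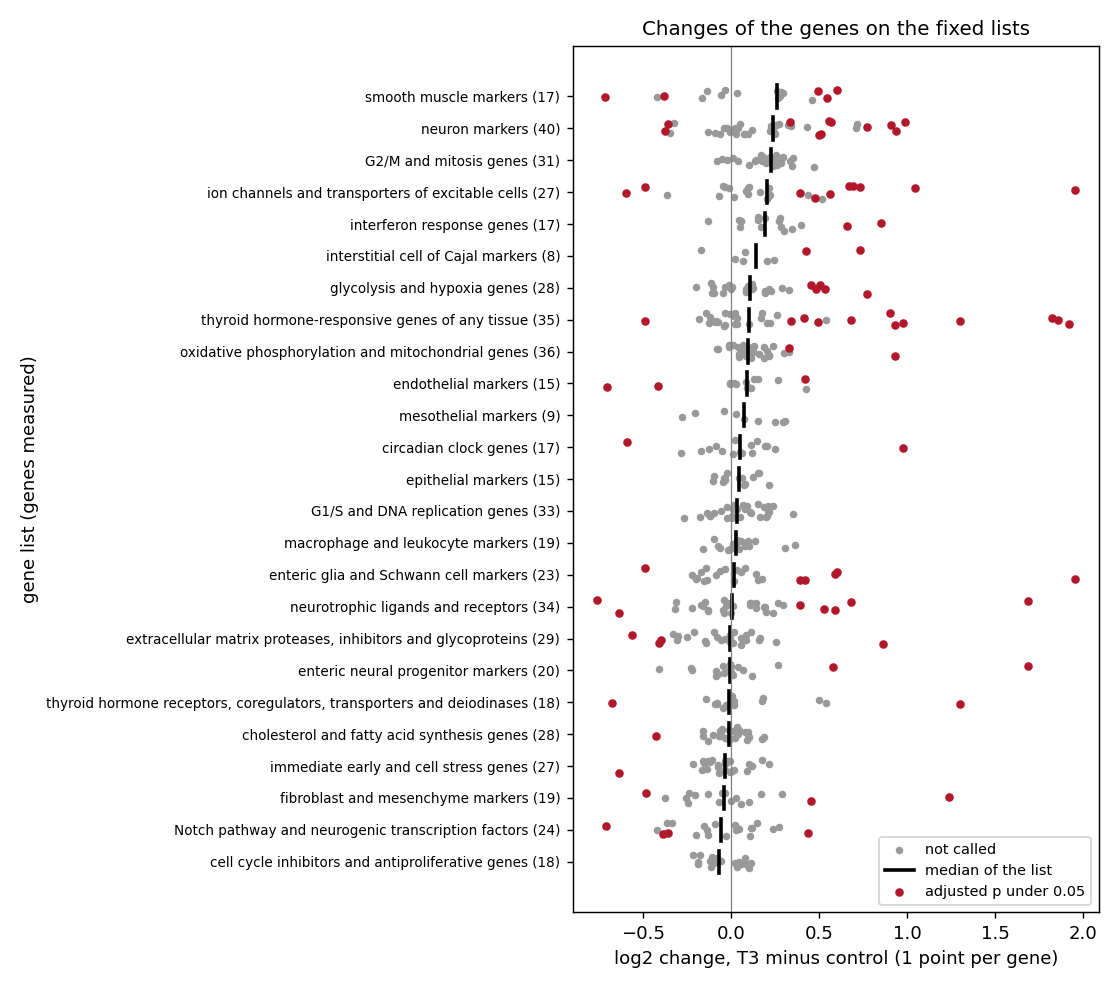
Log2 change with T3 (horizontal axis) of each measured gene on the 25 fixed lists, with genes called at adjusted p under 0.05 in red, other genes in grey and a black line at each list's median. The smooth muscle list has the highest median, 0.26, but holds genes called in both directions and was not shifted by camera. The neuron, mitosis and ion channel lists have medians of 0.23, 0.23 and 0.21, and the mitosis list holds no called gene.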

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

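The sex covariates and the test of all probe sets together were chosen after the data were seen. All 618 genes kept their direction in each of the 6 fits without 1 array and under each other setting in which they were tested at gene level. For most settings this was fixed in advance. Genes with non-overlapping groups keep their direction without 1 array or with array weights. The replicate block, trend and robust fitting and the filters leave the log2 change as it was. Only renewed normalization, centring, the mean of probe sets or a sex covariate could have turned it. The counts of 454 higher and 164 lower genes stayed within 1.5 times after renewed quantile normalization (498 and 180), centring on the median (546 and 124) or the 75th percentile (395 and 189), without the dimmest 25% (523 and 201) or 50% of genes (520 and 225), with the mean of probe sets (452 and 162), and with Xist (528 and 202) or Y-linked genes (382 and 142) as covariate. The counts moved by more with array quality weights (2451 higher and 1097 lower), which gave control replicate 1 a weight of 6.18 and 3 of the arrays 0.414 to 0.421, and with unadjusted p under 0.05 and at least 1.5-fold (230 and 77). For lower genes they also moved with trend and robust fitting (261) and with adjusted p under 0.10 (282). With all probe sets tested together, 119 were higher and 45 lower; 145 of these 164 had a single gene name, and the prior degrees of freedom fell from 4.47 to 2.53. Without 1 array the counts ranged from 134 to 516 higher and from 57 to 124 lower, lowest without control replicate 1 and highest without control replicate 2. Fits without 1 array have fewer samples; for the weights, trend and robust fitting, the cause was not tested.

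As to pairing, the choice not to take the numbers as pairs was made before the data were examined. Deviations from the group means correlated at 0.179, 0.017 and 0.000 for arrays of the same number. The first was the highest of any T3 array with a control array, while T3 replicate 3 correlated best with control replicate 2 (0.114). Eif2s3y lay at 5.90 in T3 replicate 1 and 7.29 in control replicate 1, and Xist at 9.14 and 10.27 in replicates 2. Whether same numbers shared a preparation was not settled. With a replicate block, 339 genes were higher and 133 lower, and 432 of the 618 calls were shared.

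Of the 9 list shifts, 0 passed camera with an estimated correlation between genes (adjusted p from 0.216 to 0.525). The correlations, estimated from 6 arrays, ran over these 9 lists from 0.025 for ion channels to 0.448 for mitosis genes. All lay above the preset 0.01, and a higher correlation makes camera stricter. It was not the only difference between the settings, as lists with an estimate below 0.01 show. The matrix list, at -0.016, and the glia and neurotrophic lists still had a higher unadjusted camera p with the estimate. The receptor and progenitor lists had a slightly lower one. How much of the loss a higher correlation explains was not tested. The hormone-responsive, neuron, mitosis, oxidative phosphorylation, interferon and ion channel lists passed camera without any 1 array and under the other settings of the camera test. Near 0, uncalled log2 changes turned sign: Tubb3 ranged from -0.026 to 0.086 without 1 array, Elavl4 from -0.0064 to 0.066 and Uchl1 from -0.15 to 0.061, while Elavl4 was at -0.0034 with 75th percentile centring and Uchl1 at 0.0049 with median centring and at 0.0045 with Xist as covariate; the cause was not tested. Signal over background limits dim genes, for which no detection calls are at hand.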

Other observations

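The tests on mesenchymal cells and on YAP and TAZ target genes were chosen after the result they bear on was seen, and the lists of immature neuron, synaptic and YAP and TAZ genes were drawn up after the main results; Gadd45a on the last is also on the fixed list of cell cycle inhibitors. The genes of the next paragraph were chosen after their values were seen, and no theme among them was tested.

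Among called genes on none of the fixed lists, Ace, which encodes angiotensin-converting enzyme, rose 2.73-fold, the delta opioid receptor gene Oprd1 rose 2.56-fold, the secreted protease gene Klk8 rose 2.43-fold and the serotonin receptor gene Htr2b rose 2.40-fold. Maob, an enzyme of monoamine breakdown, had a log2 change of 1.18 ± 0.15 (SE), the growth factor gene Fgf10 one of 1.17 ± 0.12 (SE) and the retinoic acid receptor gene Rarb one of 0.94 ± 0.12 (SE). The mitochondrial genes Chchd10 and Cox7a1 rose by 1.18 and 1.08, and the guanylate-binding protein genes Gbp2b and Gbp7 rose beside Gbp3 by 1.18 and 0.79, although members of this family can share probe signal. In the other direction, the nicotinic receptor gene Chrna7 fell by 0.99 on the log2 scale and the homeobox genes Dlx5 and Prrx2 by 1.01 and 0.80. The transcription factor genes Ebf2 and Osr2 fell by 0.80 and 0.63, the collagen genes Col12a1 and Col6a3 by 0.75 and 0.66, and Igfbpl1 by 0.95. Each of these genes passed limma (adjusted p from 0.000376 to 0.00862) and also passed without any 1 array.

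The 618 calls were set against the other ways to divide the 6 arrays. Of the 10 splits into 3 and 3, 1 gave as many calls, the real one, and the highest of the others gave 0; with 10 splits a share under 0.05 cannot be reached. The sex mix of the mouse pools differed between arrays, since Xist lay at 10.35, 9.14 and 9.37 in T3 replicates 1 to 3 and at 10.16, 10.27 and 8.95 in the controls, and the Y-linked gene Eif2s3y at 5.90, 7.43 and 7.65 and at 7.29, 7.49 and 7.13. Between the groups Xist differed by -0.17 (limma, adjusted p = 0.939) and Eif2s3y by -0.31 (limma, adjusted p = 0.850), and the values of the groups overlapped. As the mix did not divide the groups, this argues against it as the source of the changes. With Xist as covariate the called genes kept a median of 1.01 times their log2 change (interquartile range 0.988 to 1.03), and with the mean of Y-linked genes 0.989 times (0.952 to 1.03). With covariates so alike between the groups, ratios near 1 were likely beforehand and add little. Of the genes and receptors always named, Hr, Klf9 and Thrb rose by 1.92, 1.86 and 1.30 and passed without any 1 array. Dio3 (0.54, limma, adjusted p = 0.120) and Thra (-0.09, adjusted p = 0.652) did not pass, nor did 23 of the 35 hormone-responsive genes. Some of the 23 were dim in controls, such as Dio1 at 3.79, Dio3 at 4.44, Ucp1 at 4.52 and Thrsp at 5.36. These are not known to be above background, so their lack of a call says little. Others were bright, such as Fasn at 10.72 and Me1 at 10.21. The labels give no batch with which to test a difference in handling of the dishes.

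The neuron list was shifted upwards by camera (adjusted p = 0.350 with an estimated correlation, and 29 of 40 genes not passing) while Dcx and Insm1 were lower, calls lost without most single arrays (adjusted p up to 0.177). Under an equally larger share of neurons of all stages in the T3 spheres, immature neuron genes would be higher like the others. On new lists, 26 synaptic genes had a median log2 change of 0.22 with 24 above 0, and 21 immature neuron genes one of -0.072 with 8 above 0 and a bootstrap 95% interval of -0.17 to 0.036, which spans 0; Marcksl1 was called lower (-0.37) and Tagln3 higher (0.48), both calls lost without T3 replicate 2, T3 replicate 3, control replicate 1 or control replicate 3, and that of Marcksl1 also without T3 replicate 1 (adjusted p up to 0.140). The difference of 0.295 had p = 0.00029 in a permutation test of genes (two-sided, genes not being independent replicates). If the listed immature genes are those of neurons, this argues against an equally larger share of neurons of all stages as the whole of it. In whole spheres, a fall of such genes in other cells cannot be told apart. The test does not bear on a larger share of mature neurons alone, or on fewer immature cells. A shift from immature to mature neuronal expression is a candidate explanation: the immature list moved on balance downwards (fry, p = 0.00125), by little and not in all members, and the synaptic list upwards (fry, p = 0.0162), with p = 0.0477 and 0.0849 by camera with an estimated correlation. Whether neurons matured, mature neurons became a larger share of the spheres or single genes responded directly to T3 stays open. The shift remains a hypothesis found and tested on the same data.

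Ccn1, Ccn2, Has2, Tagln and Acta2 were picked for this weighing because they had fallen: Acta2 fell by 0.38, Tagln by 0.72, Has2, a hyaluronan synthase gene, fell by 0.96, and Ccn2 fell by 1.72 on the log2 scale, with the call of Acta2 lost without any 1 array (adjusted p up to 0.165). Tagln and Acta2 are smooth muscle genes, and the other called genes of that list were higher (Myl9 0.50, Myocd 0.54 and Myh11 0.60, with 8 higher and 3 lower adjusted over the list alone), calls that were lost without most single arrays. A smaller share of mesenchymal cells needs all genes specific to them to fall by about the same amount. The median of the fibroblast list was -0.039 (bootstrap 95% interval -0.21 to 0.058), with 7 of 19 genes above 0. It lay 0.679 above the change of Tagln and 0.342 above that of Acta2, against an SD of 0.373 over the list. Thy1, at 1.24 and also found on neurons, widens that SD. Genes picked for their fall lie below such a median by choice, so these gaps cannot decide on the share of mesenchymal cells. The interval shows only that the typical listed gene fell by less than the picked genes. A smaller loss of such cells stays open. Twist1 was called lower (-0.49, lost without any array except control replicate 1, adjusted p up to 0.117), and Fbln1, Pdgfrb and Col6a1 were lower (-0.38, -0.26 and -0.25) adjusted over the list alone. Alx4 (-1.25), Prrx2 (-0.80), Col12a1 (-0.75), Col6a3 (-0.66) and Osr2 (-0.63), on no fixed list, were called lower. Lower output of YAP and TAZ target genes, to which Ccn1 and Ccn2 belong, may be another explanation; it does not need all targets to fall alike, and the other 20 listed targets, with a median of -0.045 (camera, p = 0.136, and p = 0.338 with an estimated correlation), left it open: Nt5e was called higher (0.87), against it, and Tgfb2 lower (-0.43, lost without T3 replicate 2 or control replicate 1, adjusted p up to 0.0953).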
